A study of Homo sapiens with 4 samples.

How the data were processed

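The series holds 4 samples of T98G, an established human glioblastoma cell line, at passage 4. The cells carried a lentiviral control shRNA (shNT) or an shRNA against RBBP4. Chromatin immunoprecipitation followed by sequencing (ChIP-seq) was done for histone H3 acetylated at lysine 9 (H3K9ac), with 1 H3K9ac library and 1 input library per shRNA. The report uses the list of called regions of each of the 2 H3K9ac libraries. The input libraries were not analysed here.

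Regions were called separately in each library. The track lines carry the words macs2 and PE, per the file headers. The tools bcl2fastq 2.15.0, BWA, Picard and SICER and the builds GRCh37 and hg19 are named without a role, per the submitters' processing notes. The header and the notes thus name different peak callers, and which of them produced the lists was not settled here. The threshold, the use of the input and the caller's version are not given in the sources used here. Each deposited row gives a chromosome, a start, an end, a name and a score for the region. The score is the authors' own value per region, and the deposited files do not state its scale. Its lowest value was 2.09 in shNT and 2.00 in shRBBP4. Scores were used only to rank regions within their own list. Regions are numbered without gaps in both files. The number of reads behind each list is unknown, so a difference in depth between the libraries could not be measured.

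Positions are given on hg19, with starts counted from 1. No complete gene annotation of that build was at hand. The gene table provided is on another assembly, and no position reported here comes from it. The genomic class of regions, the test of 33 gene lists (844 genes) and values at single genes, RBBP4 among them, were planned before the data were examined and were not run. The H3K9ac status of promoters was also planned. Promoter calls, including those of the few list members found, were computed and looked at for a small set of genes placed by partial hg19 tables that come with analysis software. Overlap with CpG islands and names of chromosome bands were also computed from such tables. As a check of the build, the same genes were also placed at positions of the other assembly. All of this was set aside because those tables are not part of the data, and no result reported here uses it. Regions are named by position alone. The rule, fixed before the data were examined, takes the 5 highest-scoring regions of each library, the 5 highest-scoring ones with no region of the other library within 1 kb, and the 5 widest.

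A region was called shared when it overlapped a region of the other library by at least 1 bp. Chance overlap came from 100 random placements of the shRBBP4 regions within the span that the lists reach on each chromosome. Shares have exact Clopper-Pearson intervals, and ratios of counts have the corresponding exact conditional interval, both at 95%. These intervals cover counting error only. They treat regions as independent, although regions lie in groups, with 2.16 regions per cluster in shNT and 2.29 in shRBBP4. Clusters are regions of 1 library joined across gaps of up to 1 kb, and chromosome ratios were computed for regions and, as a choice made after seeing the data, for clusters. A chromosome was called higher or lower when its interval excluded the ratio of all other chromosomes. The 5-Mb bins, with at least 40 regions of both lists together, and the windows on chromosomes 1, 6 and 15 were also chosen after seeing the data. For the closing section, bins were permuted or rotated along the genome by at least 20 bins. With 1 library per group, no p-value across groups was computed.

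The overlap and ratio functions were tested on simulated lists. A shared share set to 59.7% of 26730 regions was recovered as 59.8%. In the simulated chromosome comparison, 23 of 23 intervals covered the ratio that had been set. The simulated regions were placed singly and counted independently, so this did not test the intervals for regions that lie in clusters. Only the counts of the second list were drawn at random there, while the intervals allow for error in both. Such coverage was therefore nearly built in. The alternatives were stricter score limits, other overlap rules, joined regions, lists of equal length, ranks by width and covered length. For lists of equal length, only the shRBBP4 list was cut, to its 26828 highest-scoring regions. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used.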

Results

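H3K9ac, a histone mark found at active promoters, was profiled by ChIP-seq in T98G glioblastoma cells that expressed a control shRNA (shNT) or an shRNA against RBBP4, a histone-binding protein found in several chromatin complexes, histone deacetylase complexes among them. The comparison asks how the H3K9ac landscape differs between the control and the RBBP4 shRNA cells. Each shRNA is represented by 1 H3K9ac library, so no difference between the libraries has a replicate check. The depth of the libraries is unknown. The level of RBBP4 was not analysed here.

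The shRBBP4 library had more H3K9ac regions than the shNT library, and they covered more of the genome. It held 39303 regions against 26828, a ratio of 1.46 (95% interval 1.44 to 1.49, counting error only). The regions covered 11.9 Mb in shRBBP4 and 7.89 Mb in shNT, a ratio of 1.51. Their widths were similar, with a median of 213 bp in shRBBP4 and 210 bp in shNT. Regions wider than 1 kb made up 2.62% of the shRBBP4 list and 2.14% of the shNT list. Joined across gaps of up to 1 kb, the regions formed 17155 clusters in shRBBP4 and 12429 in shNT, a ratio of 1.38 (1.35 to 1.41). Without known depths, a difference in the number of called regions cannot be read as a difference in the amount of acetylation.

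The widest regions of each library had counterparts in the other. The widest shNT region, on chromosome 11 from 65266641 to 65271216, spanned 4576 bp, and shRBBP4 regions covered 96.4% of it. The widest shRBBP4 region, on chromosome 5 from 57749557 to 57755808, spanned 6252 bp and was 76.0% covered by 8 shNT regions. A region of 4101 bp on chromosome 17, from 57915365 to 57919465, was the third widest in shNT, and its shRBBP4 counterpart of 3814 bp, from 57915386 to 57919199, was the fifth widest there. The largest joined cluster of both lists together spanned 32.5 kb on chromosome 22, from 46450421 to 46482946. It held 29 shNT regions covering 22.9 kb and 24 shRBBP4 regions covering 27.6 kb. Of the 5 windows of 1 Mb with most regions, 4 were the same in both libraries. The window from 26 to 27 Mb on chromosome 6 had 120 regions in shNT and 136 in shRBBP4, and that from 65 to 66 Mb on chromosome 11 had 118 and 145. Across 2292 windows the counts of the 2 libraries had a Spearman correlation of 0.89, computed across windows, which are not independent replicates.

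Most shNT regions were also called in shRBBP4, whereas about as many shRBBP4 regions lacked an shNT counterpart as had one. Of the shNT regions, 20656 overlapped an shRBBP4 region (77.0%, 95% interval 76.5 to 77.5). Of the shRBBP4 regions, 19669 overlapped an shNT region (50.04%, 49.5 to 50.5). These shares depend on the length of the lists. In lists of equal length they were 67.2% of shNT and 60.9% of shRBBP4 regions. Random placement along each chromosome gave a mean of 0.957% for shNT and 0.581% for shRBBP4. It ignores that the mark lies at active promoters and that regions lie in groups, so it sets a low bar. Within 1 kb, 93.8% of shNT regions and 74.3% of shRBBP4 regions had a counterpart, which left 1675 shNT and 10117 shRBBP4 regions without one. Of 18106 clusters made from both lists together, 10454 held regions of both libraries, 1315 held only shNT regions and 6337 held only shRBBP4 regions. Clusters of both libraries had a median span of 1498 bp, against 158 bp for shNT alone and 207 bp for shRBBP4 alone. Part of this difference is built in, because a cluster of both libraries must join regions of each list. With a reciprocal overlap of at least 50%, the shared share fell to 39.6% of shNT and 27.0% of shRBBP4 regions.

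Shared regions ranked higher in their own list than regions that overlapped none of the other library. In shNT the median score percentile was 58.1 for shared and 31.0 for other regions, and in shRBBP4 it was 68.8 and 34.7. In the highest-scoring 10% of each list, 99.0% of shNT regions (98.5 to 99.3) and 93.5% of shRBBP4 regions (92.7 to 94.3) were shared. In the lowest-scoring 10%, the shares were 56.2% and 23.7%. Shared regions were also wider, with medians of 246 against 152 bp in shNT and 303 against 164 bp in shRBBP4. Score rose with width (Spearman correlation 0.49 in shNT and 0.52 in shRBBP4). Wide regions meet a rule of 1 bp more easily, and score was not separated from width.

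**Figure D1:**
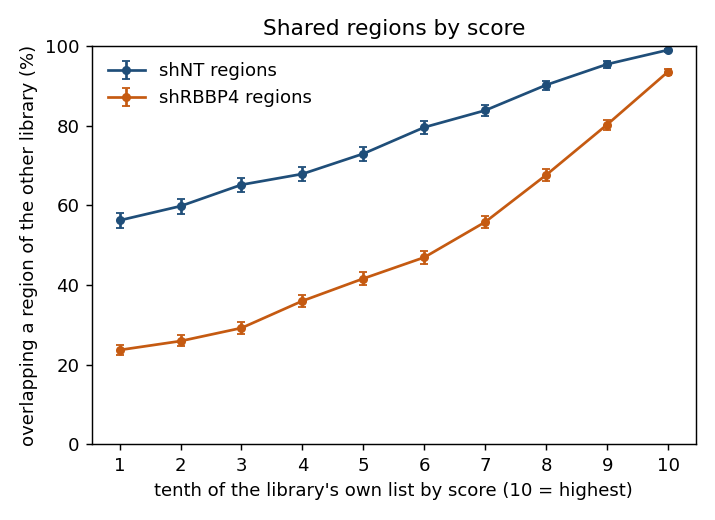
Percentage of regions that overlapped a region of the other library (y axis), by position in the library's own list ranked by score and divided into 10 equal parts (x axis, 10 the highest), for 1 library per group. Bars are exact 95% intervals for counting error only; the share climbs from 56.2% to 99.0% in shNT and from 23.7% to 93.5% in shRBBP4.

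The highest-scoring regions were found in both libraries, with 1 exception by rank. The top shNT region, on chromosome 17 from 45000274 to 45000426, had a counterpart at percentile 99.7 of the shRBBP4 list. The top shRBBP4 region, on chromosome 20 from 34042669 to 34042851, had one at percentile 99.96 of the shNT list. A further pair of strong regions on chromosome 20, from 49575111 to 49575303 in shNT and from 49573654 to 49575328 in shRBBP4, stood among the first 5 of both lists. The exception was on chromosome 15, from 30917687 to 30918180. This region stood at percentile 99.99 in shRBBP4, while the best overlapping shNT region stood at percentile 61.0.

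Strong regions without any counterpart within 1 kb were found mainly in shRBBP4. Those at the highest scores lay on chromosome 14 from 50328071 to 50328835 and on chromosome 15 from 59587470 to 59588397, from 33117308 to 33118243, from 52385946 to 52386145 and from 33066606 to 33067192. Their percentiles in shRBBP4 were between 98.4 and 99.4. The corresponding shNT regions stood lower in their list, at percentiles 89.6 to 94.4, led by a region on chromosome 1 from 155579440 to 155579727. The others lay on chromosome 8 from 42196014 to 42196193 and, again, on chromosome 15. Those on chromosome 15 ran from 63797670 to 63797931, from 101836159 to 101836444 and from 40862183 to 40862375. Above percentile 90, 121 of 4072 shRBBP4 regions had no counterpart (2.97%, 2.47 to 3.54), against 4 of 2699 in shNT (0.148%, 0.0404 to 0.379). Chromosome 15 held 17 of the 121 and 2 of the 4. The shNT list is shorter and its depth is unknown, so these shares do not measure gain or loss of the mark.

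The excess of shRBBP4 regions was unequal along the genome. Chromosome 14 had 1002 regions in shRBBP4 and 497 in shNT, a ratio of 2.02 (1.81 to 2.25), and chromosome 10 had a ratio of 1.91 (1.75 to 2.08). Chromosome 7 had 1823 and 1660 regions, a ratio of 1.10 (1.03 to 1.17), chromosome 8 a ratio of 1.15 (1.06 to 1.24), chromosome 16 of 1.17 (1.09 to 1.26) and chromosome X of 1.20 (1.04 to 1.37). Of 23 chromosomes, 9 were higher than the ratio of the others (2, 3, 4, 6, 10, 14, 19, 20 and 22), 6 were lower (1, 7, 8, 13, 16 and X) and 8 were within it. Counting clusters in place of regions left 5 higher (2, 3, 10, 14 and 20) and 5 lower (1, 7, 8, 16 and X). The calls on chromosomes 4, 6, 13, 19 and 22 ended when clusters were counted. In lists of equal length the calls on 4 and 6 ended and chromosome 15 was called higher. In the strongest 5000 regions of each list the calls on 4 and 22 ended and chromosomes 5 and 15 were called higher. There, chromosome 4 lay farther from the rest (log2 ratio relative to the rest 0.42, against 0.19 in the full lists), but with a wider interval.

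**Figure D2:**
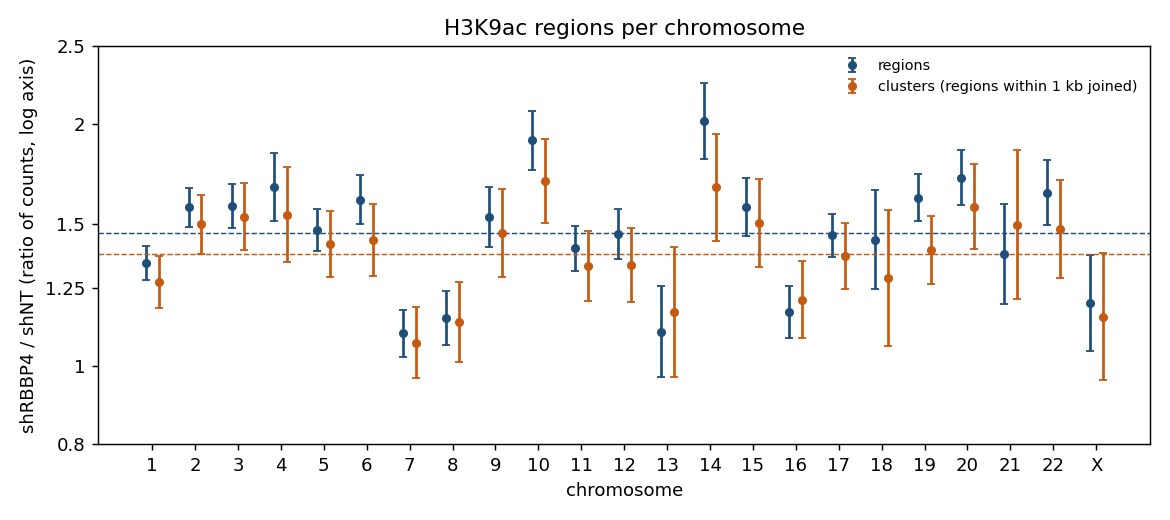
Ratio of shRBBP4 to shNT counts (y axis, log scale) for each chromosome (x axis), from 1 library per group, for regions and for clusters of regions joined within 1 kb. Bars are exact 95% intervals for counting error only and dashed lines the ratios of the whole lists, 1.46 and 1.38; chromosomes 10 and 14 lie above and chromosomes 7, 8 and 16 below in both counts.

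On chromosomes 7, 8, 16 and 20 most bins lay on the same side of the whole-list ratio as the chromosome. On chromosome 20, 13 of 13 bins of 5 Mb had a ratio above that of the whole lists. The ratio was below it in 25 of 28 bins of chromosome 7, in 14 of 15 of chromosome 16 and in 21 of 24 of chromosome 8. Other chromosomes were similar, with 11 of 12 bins above it on 14, 20 of 25 above on 10 and 10 of 11 below on 13. Chromosome 11, within the ratio of the others as a whole, also had 18 of 23 bins below. These counts give only the side of the ratio. Each chromosome's total comes from the same regions, so part of the agreement is built in. The lowest bin of chromosome 20 was at 1.474, against 1.465 for the whole lists. Of all 465 bins, 399 had an interval that included the ratio of the rest. Chromosome 1 differed by regions between stretches that were chosen after seeing the data. Its first 40 Mb had a ratio of 1.77 (1.59 to 1.96), against 1.15 (1.05 to 1.26) from 40 to 120 Mb. In clusters these ratios were 1.46 (1.26 to 1.70) and 1.16 (1.01 to 1.33), and the intervals overlapped. The choice of stretches makes all of these intervals too narrow. The highest-ratio bins included chromosome 14 from 75 to 80 Mb, with 86 regions in shRBBP4 and 19 in shNT, and chromosome 5 from 165 to 170 Mb, with 66 and 15. Chromosome 8 from 70 to 75 Mb had fewer regions in shRBBP4, 31 against 51. Of 465 bins, 66 lay outside the ratio of the rest. The nominal error rate of the intervals would place about 23.3 there if regions were independent. Regions lie in clusters and the bins were not recounted in clusters, so the 66 cannot be read as an excess.

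A block on chromosome 15 held 3 of the strong shRBBP4 regions named above, those between 30 and 34 Mb. From 25 to 35 Mb, shRBBP4 had 147 regions and shNT 45, a ratio of 3.27 (2.32 to 4.67), with 65 and 23 clusters. Of these regions, 26 stood above percentile 90 in shRBBP4 and 3 in shNT. In the window from 33 to 34 Mb there were 57 regions covering 23.5 kb in shRBBP4 and 4 covering 0.758 kb in shNT. The next window, from 34 to 35 Mb, had 12 and 16. The block was picked because it stood out, so its interval is too narrow.

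**Figure D3:**
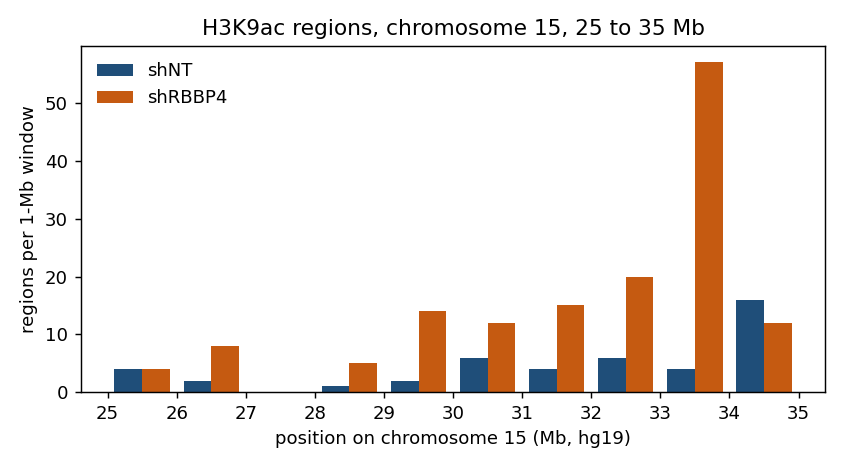
Number of H3K9ac regions (y axis) in each 1-Mb window of chromosome 15 from 25 to 35 Mb on hg19 (x axis), in the shNT and the shRBBP4 library. The shRBBP4 bar reaches 57 at 33 to 34 Mb, where shNT has 4.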

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

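No paired analysis was possible because each group has 1 library. The genomic class of regions and the test of gene lists, with their alternatives, were not run, for want of a complete annotation of the build. Promoter calls and their alternatives, computed for a small set of genes, were set aside and are not reported. Covered length per chromosome has no counting interval, so it gave no count of chromosomes. Counting clusters and taking the strongest 5000 regions were chosen after seeing the data.

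The higher-scoring 50% of each list, fewer regions by construction, held 13414 shNT and 19651 shRBBP4 regions with median widths of 296 and 307 bp, and covered 5.17 and 7.97 Mb. Joining regions within 1 kb gave 12429 and 17155 clusters, median spans of 651 and 748 bp and spans of 12.1 and 18.3 Mb in all, gaps included, and a ratio of 1.38. The shared share of shNT and shRBBP4 regions was 70.2% and 45.2% when 50% of the shorter region had to overlap, 39.6% and 27.0% with reciprocal overlap, 93.8% and 74.3% within 1 kb, 67.2% and 60.9% in lists of equal length, and 89.8% and 68.8% for the higher-scoring 50% looked up in the full other list. Between the higher-scoring 50% of both it was 75.3% and 49.8%. The gap in median percentile between shared and other shRBBP4 regions was 32.9 by width and 24.8 within 1 kb. The gap stayed positive in both libraries in these 2 settings, the only ones in which it was computed. Clusters left 5 chromosomes higher than the rest, and 2 of the 15 called chromosomes then lay farther from the rest than by regions. The log2 ratio relative to the rest went from 0.15 to 0.02 on chromosome 19, from 0.14 to 0.06 on 6 and from 0.19 to 0.17 on 4. It went from -0.41 to -0.25 on 13 and from 0.17 to 0.10 on 22. The cause of these changes was not tested. In lists of equal length the log2 ratio of chromosome 4 relative to the rest was 0.04. The 15 chromosomes called kept their direction in lists of equal length, in clusters, in the strongest 5000 regions and by covered length, and 13, 10 and 13 of them kept the call in the first 3 of these. Unknown depth limits every comparison of region number.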

Other observations

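All tests in this part were chosen after the results they bear on had been seen.

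In the strongest 5000 regions of each list, 14 of the 15 called chromosomes lay farther from the ratio of the rest than in the full lists. The exception was chromosome 22 (log2 ratio relative to the rest 0.15, against 0.17), and chromosome 10 moved little (0.42, against 0.40). Fewer regions also give wider intervals. In these lists chromosome 8 had 251 in shNT and 133 in shRBBP4, a ratio of 0.530 (95% interval 0.426 to 0.656, counting error only). Chromosome X had 50 and 14, chromosome 7 had 416 and 242, and chromosome 20 had 244 and 353. In the strongest 1000, chromosome 20 had 61 in shNT and 125 in shRBBP4, and chromosome 8 had 51 and 15, while the called chromosomes 2, 3, 7, 19 and 22 lay nearer to equal numbers than in the strongest 5000, with ratios of 1.13, 1.21, 0.690, 1.13 and 1.02.

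The ratio of shRBBP4 to shNT regions differed between chromosomes. A difference in depth or threshold that changes counts by the same factor on all chromosomes would leave no such structure. In lists of equal length, 42.0% of the variance of the log2 ratio of 417 bins lay between chromosomes. The share was at most 12.7% in 10000 permutations of the bins. It was at most 34.1% in 378 rotations of the bins along the genome, which keep neighbours together. Only the shRBBP4 list was cut to reach equal length, and the cut acted unequally. It took chromosome X from 466 to 256 regions and chromosome 19 from 2315 to 1699. Part of the 42.0% may come from the cut, and the share was not computed in the full lists. In the full lists the ratio ran from 1.10 on chromosome 7 to 2.02 on chromosome 14. Those full-list ratios argue only against such a common factor. A depth or threshold change may still act unequally, because the strength of regions differed between chromosomes. The strongest 5000 shNT regions included 416 of 1660 on chromosome 7, 244 of 1014 on 20, 52 of 497 on 14 and 53 of 442 on 13. Chromosomes 7 and 20 had similar shares but ratios of 1.10 and 1.71 in the full lists. Chromosomes 13 and 14 had similar shares but ratios of 1.10 and 2.02. On these chromosomes, picked after seeing the data, the ratio did not follow this share. An effect through region strength was not tested across all chromosomes. Bins were then split into 10 classes of region density, and the mean of each class was subtracted. This left 41.1% of the variance between chromosomes, against at most 13.4% in permutations and 33.8% in rotations. Density was counted from the same 2 lists whose ratio was tested, so this cannot exclude an effect that acts through density. Neighbouring bins also deviated together within chromosomes (correlation 0.23, highest permuted value 0.19), as either a copy number difference between the 2 cell populations or a change of acetylation over whole blocks may give. Those cannot be told apart from the ChIP lists of 1 library per group without the inputs, and GC content was not tested.

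The shRBBP4 list held more regions than the shNT list. Higher depth or enrichment of that library may add weak regions, and the shRBBP4 regions with no shNT region within 1 kb had a median score percentile of 33.3. The shNT regions with no shRBBP4 region within 1 kb were also weak, at 27.4, so this value does not bear on the depth of either library. A gain of acetylation after RBBP4 depletion stays open and was not tested. With 1 library per group and unknown depth, the effect of depth cannot be told apart from that of the shRNA.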
